A study of Mus musculus with 8 samples.

How the data were processed

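The deposited raw table holds a count per Ensembl gene for each of the 8 libraries, and these counts were used as they are. The deposited normalized table holds log2 values made by the authors, and 6 further columns of it were not used. Per the submitters' processing notes, the tools named are FastQC, Trimmomatic 0.33, STAR 2.4.0a, featureCounts 1.4.5-p1 of Subread and DESeq2, without their roles or order, and the builds named are mm10 and GRCm38. The strand setting and the annotation release are not given in the sources used here. Per the labels, the protocol names a stranded mRNA kit and a total RNA kit without saying which library each made. The normalized table was checked against the counts and entered 1 alternative inside each library set only, because each gene has the same mean in both sets there (largest difference 5.0e-09 over 15183 genes). Of the 15183 identifiers, 15165 have a symbol in the gene table, and 13618 have a RefSeq span on GRCm38.p6, from which the coordinates come.

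Counts were scaled with TMM factors of edgeR 4.0.16 (R 4.3.3), and genes with low counts were removed with filterByExpr by group, which left 13633 genes. One quasi-likelihood model with a coefficient per group was fitted to all 8 libraries (robust), so that the groups share the dispersion. Each comparison was tested two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. TMM factors ran from 0.241 to 0.470 in the first library set and from 2.876 to 3.299 in the second, where the 20 genes with an mt- symbol had 0 counts. CPM are counts scaled to a library size of 1e6 after TMM, and log2 CPM used a prior count of 2. A fold against a group with 0 counts was computed with 3 counts in each of its libraries and is a lower bound. P-values measure the spread between libraries, which the labels call biological replicates, and floors cover counting error only.

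Before the data were examined, the comparisons between groups, 36 gene lists and the rule for naming genes were fixed. So were the tests and alternatives, except the sex term and the others stated below to be chosen after the data were seen. The lists cover the reprogramming factors, the pluripotency network, epithelial genes, fetal and stress cardiac genes, the adult contractile apparatus, calcium handling and ion channels, fatty acid oxidation, ketone bodies, the tricarboxylic acid cycle, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, mitochondrial ribosomal proteins, glycolysis, serine and one-carbon synthesis, S phase, mitosis, p53 targets, the integrated stress response, NRF2 targets, immediate early genes, YAP targets, the interferon response, inflammatory genes, extracellular matrix, cytosolic ribosomal proteins, ribosome biogenesis, and non-polyadenylated transcripts. They also cover markers of fibroblasts, endothelium, smooth muscle and pericytes, macrophages, neutrophils and lymphocytes, erythroid cells, Schwann cells, epicardium and atrium. Lists with at least 3 tested genes (35 of them) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, beside camera with an estimated correlation. Of 14 neutrophil and lymphocyte markers 3 are in the table, too few to test. Genes named are the 4 factors, the 8 largest rises and falls per main comparison (5 in the others) among called genes with a mean of at least 5 CPM over the 2 groups, separated replicates and a symbol that is not a predicted model, and up to 4 members of a list with the smallest p, and not every gene this rule covers is printed. Genes named outside that rule, chosen after their values were seen, are Hmmr, Top2a and Myh7 in the withdrawal comparison, Arntl, Comp and Myl6b, the macrophage markers Mrc1 and Lyz2, and, in the comparisons across library sets, the picks among genes counted in both sets, since the rule itself picked genes at 0 in 1 set.

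In a self-test, 200 genes of simulated counts were changed 2-fold or 4-fold. The model recovered 57 and 98% of the 2-fold and 4-fold changes in the 12-day against uninduced comparison (11.4% false calls) and 33 and 89% in the withdrawal against 6-day comparison (8.3% false calls). A changed list was called in each comparison, also with an estimated correlation, and 1 unchanged list was called in 12-day against withdrawal. The simulated genes were drawn independently, so this does not show how either form of camera performs where genes vary together. DESeq2 1.42.0, limma-voom, other scalings and filters, a sex term, a replicate block and the removal of each library served as alternatives. The labels list no group given doxycycline without the construct. Paralogs such as Myh6 and Myh7, Rpl3 and Rpl3l, or the ribosomal proteins are uncertain where reads could be split between them. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.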

Results

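RNA was sequenced from cardiomyocytes, the contractile muscle cells of the heart, isolated from adult mice (12 to 16 weeks of age) that carry an inducible reprogramming construct. A Cre driver opens the construct in these cells, and doxycycline then switches on Pou5f1 (Oct4), Sox2, Klf4 and Myc, the 4 transcription factors that can turn somatic cells into pluripotent cells. The 8 libraries form 4 groups of 2. One group received no doxycycline (uninduced), 1 group received it for 6 days (6-day), 1 group for 12 days (12-day), and 1 group received it for 6 days and was then kept for 6 days without it (withdrawal).

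The libraries fell into 2 sets of 4 that the labels do not name. The first set holds the uninduced libraries, with total counts of 41485326 and 28333847, and the 12-day libraries, with 21596097 and 36443373. The second set holds the 6-day libraries, with 1517079 and 1477245 counts, and the withdrawal libraries, with 1692421 and 1615757. In the first set 76.18 to 86.29% of the counts came from mitochondrially encoded transcripts, and the mitochondrial ribosomal RNA mt-Rnr2 alone took 62.98 to 70.27%. In the second set the 20 mitochondrial genes of the table had 0 counts in each library. Outside these genes the depth differed by 4.4-fold, from 1477245 counts in a 6-day library to 6486782 in an uninduced library. The table lists 15183 genes, of which 2439 stand at 0 in all 4 libraries of the first set and 239 in all 4 of the second. Whether such a 0 means not expressed or not counted in that set is not known, so calls that rest on these genes may come from how the table was made. Comparisons of the 12-day with the uninduced group and of the withdrawal with the 6-day group lie inside a set. In the other 4 comparisons the set and the group cannot be told apart.

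The sex of the animals also differed between groups. Both uninduced libraries held Y-linked transcripts (2435 and 2223 counts), whereas both 12-day libraries held Xist, the RNA of the inactive X chromosome (2736 and 3389 counts), and 1 and 2 Y-linked counts. The 6-day group had 1 library with Y-linked transcripts (759 counts) and 1 with Xist (1090), and the withdrawal group had 1 of each as well (879 and 1215).

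Pou5f1, Sox2 and Myc followed the doxycycline schedule, and Klf4 did so less clearly. Pou5f1, a core factor of pluripotency, stood at 32.4 ± 5.99 CPM (mean ± SD, n = 2, as for all values below) in the 12-day and 37.2 ± 5.27 CPM in the 6-day libraries, and had 0 counts in both uninduced libraries. Sox2, its partner on DNA, stood at 26.8 ± 5.55 and 20.8 ± 2.94 CPM, and also had 0 counts in both uninduced libraries. Myc, which drives growth and proliferation, stood at 36.2 ± 5.34 CPM in the 12-day, 22.4 ± 3.25 in the 6-day, 1.25 ± 0.890 in the withdrawal and 0.494 ± 0.00746 in the uninduced libraries. Klf4 had a clear baseline of 21.3 ± 10.6 CPM without induction, and stood at 50.2 ± 11.8 CPM after 12 days, 36.7 ± 2.78 after 6 days and 15.3 ± 1.02 after withdrawal. After withdrawal the counts were 0 and 4 for Pou5f1 and 1 and 2 for Sox2. A count of 0 allows up to 3 counts per library, which is 0.294 to 0.302 CPM in the first set and 0.617 to 0.625 CPM in the second. On GRCm38 the genes lie on chromosome 17 at 35506032 to 35510777 (Pou5f1, ENSMUSG00000024406), chromosome 3 at 34649995 to 34652461 (Sox2, ENSMUSG00000074637), chromosome 4 at 55527137 to 55532475 (Klf4, ENSMUSG00000003032) and chromosome 15 at 61985341 to 61990361 (Myc, ENSMUSG00000022346). The counts do not separate transcripts of the construct from those of the mouse genes.

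**Figure D1:**
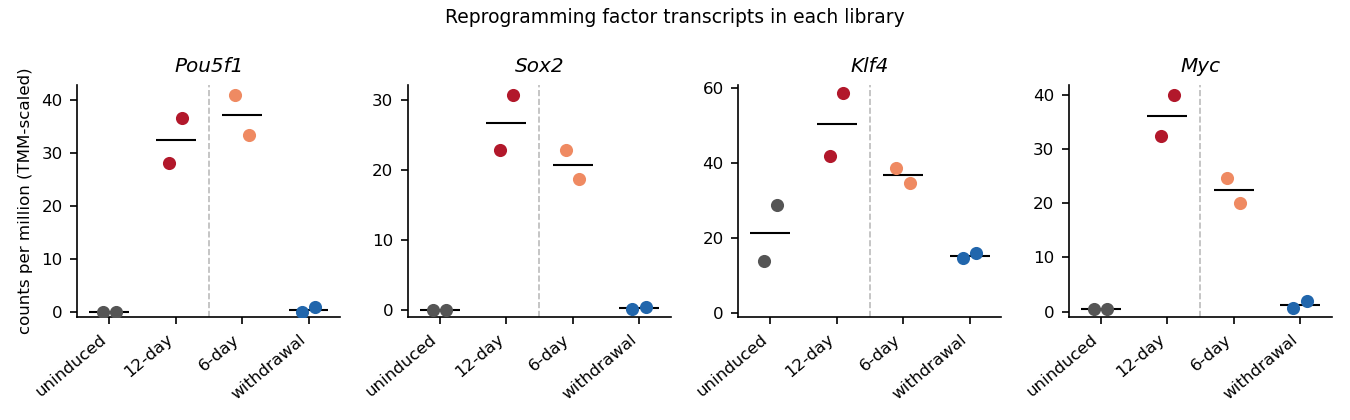
TMM-scaled CPM of Pou5f1, Sox2, Klf4 and Myc in each library, where points are libraries, horizontal lines are group means and the dashed line is the border between the library sets. Pou5f1 and Sox2 had 0 counts in both uninduced libraries and at most 4 counts in a withdrawal library.

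Inside the first set, Pou5f1 was at least 109-fold and Sox2 at least 90.3-fold higher in the 12-day than in the uninduced libraries (edgeR adjusted p = 5.39e-05 and 1.57e-05), counting 3 per library for the uninduced zeros. Myc rose by a log2 fold change of 6.15 (SE 0.36, adjusted p = 1.57e-05). Klf4 rose by 1.24 (SE 0.30, adjusted p = 0.0180), a call that ended with a term for sex (1.38, adjusted p = 0.155, so that the change was not smaller) and without 12-day replicate 2 (0.97, 0.130). Inside the second set Pou5f1, Sox2 and Myc fell after withdrawal, with log2 fold changes of -6.43 (SE 0.53), -5.99 (0.44) and -4.16 (0.37), and edgeR adjusted p of 0.00165, 0.00159 and 0.00159. Klf4 was not called there (-1.26, SE 0.33, adjusted p = 0.0615), but was called lower with DESeq2 (0.0126), with these 2 groups alone (0.0105), with a replicate block (0.0242) and by limma on the deposited normalized values (0.0453).

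The 12-day against uninduced comparison asks how adult cardiomyocytes differ after 12 days of doxycycline and factor expression. Since no group received doxycycline without the construct, effects of the drug cannot be told apart from those of the factors, here or below. Genes of cell division and some of the fetal heart were higher, and genes of fatty acid oxidation and respiration and some of ion transport were lower. Top2a, the topoisomerase that untangles replicated DNA, stood at 81.1 ± 40 CPM against 1.28 ± 0.960 CPM. Myh7, the slow myosin heavy chain of the fetal mouse ventricle, rose 31.2-fold, from 161 ± 20.9 to 5040 ± 147 CPM, and Nppa, the atrial natriuretic peptide, rose 33.8-fold, from 3.30 ± 1.14 to 112 ± 22.0 CPM. Ech1, an auxiliary enzyme of fatty acid oxidation, was 4.61-fold lower, at 52.9 ± 6.23 against 244 ± 42.2 CPM. Of 13633 genes tested, edgeR called 2962 at an adjusted p under 0.05, 1578 higher and 1384 lower, of which 1101 and 726 changed at least 2-fold.

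Among called genes with a mean of at least 5 CPM over the 2 groups and separated replicates, the factors aside, the 8 largest rises were mostly in genes of mitosis. Hmmr, a spindle protein, rose from 0.196 ± 0.277 to 69.2 ± 42.7 CPM (log2 fold change 8.34, SE 0.83, edgeR adjusted p = 0.000307). The others were the spindle protein Dlgap5 (6.99), Uhrf1, which guides DNA methylation after replication (6.81), the spindle proteins Ckap2l (6.72) and Knstrn (6.26), the scaffold Iqgap3 (6.67), the kinetochore protein Kntc1 (6.21) and Anln, an actin binder of the cleavage furrow (6.20). In the list of G2, mitosis and cytokinesis, 34 of 35 tested genes rose, and 34 did so when adjusted over the list alone, with a median log2 fold change of 5.18 (5.08 with genes at 0 set to their bound). Bub1b, a spindle checkpoint kinase, rose by 5.49 (SE 0.53, edgeR adjusted p = 0.000152). In the list of DNA replication and S phase 22 of 30 rose (26 when adjusted over the list alone, median 2.21), among them the helicase subunit Mcm6 (3.09) and the polymerase subunit Pole (2.86). With camera the adjusted p was 5.70e-29 for the mitosis list and 1.07e-16 for the S phase list, and adjusted p = 0.39 and 0.21 with an estimated correlation.

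Fetal and stress genes of the heart rose in part. Of 30 tested, 12 were higher and 1 lower (15 and 1 when adjusted over the list alone, median 0.99, camera adjusted p = 2.02e-08; adjusted p = 0.21 with an estimated correlation). Besides Myh7 and Nppa these included Tnnt1, the slow skeletal troponin T (5.59), and Acta2, smooth muscle actin (3.86). The atrial marker list, which also holds Nppa, had 1 member higher and 2 lower of 8 and was not called (median -0.49, mean 0.04, adjusted p = 0.639). Adult contractile genes were mixed, with 2 of 25 higher and 6 lower (2 and 6 when adjusted over the list alone), a median of -0.40 (-0.05 with library totals as the scaling) and no call by camera (adjusted p = 0.0577). Tcap, which anchors titin at the Z disc, fell by 1.48, Tnni3, the cardiac troponin I, fell by 1.49 and Mylk3, the cardiac myosin light chain kinase, fell by 0.89, whereas the Z disc protein Synpo2l rose by 2.20; with library totals as the scaling the calls of Tnni3 (adjusted p = 0.0505) and Mylk3 (0.437) ended. Of the calcium handling and ion channel genes 13 of 27 fell (15 lower and 2 higher when adjusted over the list alone, median -0.59, camera adjusted p = 4.11e-07, and adjusted p = 0.52 with an estimated correlation). With library totals as the scaling the median of this list was -0.24. Scn4b, a sodium channel subunit, had the largest fall among called genes with a mean of at least 5 CPM over the 2 groups and separated replicates, from 34.8 ± 16.3 to 0.643 ± 0.624 CPM (log2 fold change -5.72, SE 0.58, edgeR adjusted p = 0.000351). Kcnip2, a subunit of the transient outward potassium channel, fell from 104 ± 16.0 to 16.6 ± 4.11 CPM (-2.65), Hrc, a calcium binding protein of the sarcoplasmic reticulum, fell by 2.10, and the inward rectifier Kcnj2 fell by 1.56.

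Fuel use genes were lower across several lists. In fatty acid oxidation 29 of 32 genes fell (30 when adjusted over the list alone, median -1.36), in the tricarboxylic acid cycle 15 of 25 (22, median -0.71), and in nuclear-encoded oxidative phosphorylation 53 of 73 fell and 1 rose (58 and 1, median -0.88). The camera adjusted p of these 3 lists was 2.15e-24, 2.85e-10 and 1.26e-19, and adjusted p = 0.35, 0.52 and 0.52 with an estimated correlation. Acaa2, the last thiolase of the fatty acid spiral, fell from 442 ± 72.0 to 101 ± 5.72 CPM (-2.13, SE 0.17, edgeR adjusted p = 5.69e-05). Acadm, a medium chain acyl-CoA dehydrogenase, fell by 1.80 and Cpt2, which hands fatty acids to the matrix, by 1.62. The complex I subunit Ndufs7 (-1.60), the cytochrome oxidase subunit Cox7a1 (-1.70), the isocitrate dehydrogenase subunit Idh3b (-1.22) and the succinate dehydrogenase subunit Sdha (-0.98) fell as well. With library totals as the scaling the medians of the 3 lists were -0.98, -0.35 and -0.49, and the calls of Sdha (-0.62, adjusted p = 0.398) and Idh3b (-0.85, 0.188) ended. Of the ketone body genes 3 of 6 fell (4 when adjusted over the list alone, median -0.70, -0.36 with library totals, camera adjusted p = 0.0327, and adjusted p = 0.52 with an estimated correlation). Mitochondrial ribosomal proteins, 9 of 44 lower (9 when adjusted over the list alone), had a median of -0.20 that turned to 0.13 with library totals as the scaling (camera adjusted p = 0.0247, 0.108 with library totals; adjusted p = 0.73 with an estimated correlation). Without uninduced replicate 1 or 12-day replicate 2 neither the ketone body list (adjusted p = 0.217 and 0.0688) nor the mitochondrial ribosomal list (0.444 and 0.153) was called. Further large falls were in the potassium channel subunit Kcnv2 (-4.83), the carboxylesterase Ces1d (-4.22), Rpl3l, a ribosomal protein of striated muscle (-3.86), the calcium channel Cacna1s (-3.39), the glycerol channel Aqp7 (-3.35) and the carbonic anhydrase Car4 (-3.33, not called without 12-day replicate 2, adjusted p = 0.0631).

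Biosynthetic genes rose in part. In serine, one-carbon and nucleotide synthesis 8 of 24 rose and 1 fell (11 and 1 when adjusted over the list alone, median 0.60), in ribosome biogenesis 12 of 24 rose (17, median 0.78), and in cytosolic ribosomal proteins 23 of 52 rose (30, median 0.60). The camera adjusted p of these lists was 2.53e-05, 9.48e-08 and 1.31e-08, and adjusted p = 0.21, 0.52 and 0.52 with an estimated correlation. Psat1, an enzyme of serine synthesis, rose from 0.398 ± 0.286 to 11.9 ± 0.875 CPM (log2 fold change 4.85, SE 0.42, edgeR adjusted p = 8.36e-05), and Mthfd2, a mitochondrial folate enzyme, rose by 4.06. Npm1 (1.69) and Gnl3 (1.80), both nucleolar proteins, and the ribosomal proteins Rpl3 (2.56) and Rplp1 (1.43) rose too.

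Part of the matrix and YAP target genes rose, and part of the endothelial markers fell. In the extracellular matrix list 12 of 25 rose (17 when adjusted over the list alone, median 1.36, camera adjusted p = 9.98e-08; adjusted p = 0.52 with an estimated correlation), including Postn, a matrix protein of activated fibroblasts (3.87), the crosslinking enzyme Lox (4.94), elastin (Eln, 2.97) and the collagen Col3a1, from 20.3 ± 11 to 112 ± 46.3 CPM (2.46). Of 14 fibroblast markers, 2 of which other lists also hold, 4 were higher (4 when adjusted over the list alone, median 0.29), and the list was not called (adjusted p = 0.0888). Among the YAP targets 5 of 16 rose and 1 fell (5 and 1 when adjusted over the list alone, median 0.24, camera adjusted p = 0.0259; adjusted p = 0.52 with an estimated correlation), with Ccn2 (3.61), Tgfb2 (3.06) and Nt5e (2.66), and the list was not called without any 1 of the second set libraries, which only share the dispersion (adjusted p = 0.0896 and 0.0800 without 6-day replicates 1 and 2, 0.106 and 0.102 without withdrawal replicates 1 and 2), nor with a replicate block (0.0972). Of the endothelial markers 9 of 16 fell (14 when adjusted over the list alone, median -1.83, camera adjusted p = 0.000121; adjusted p = 0.61 with an estimated correlation). That list was not called with a term for sex (adjusted p = 0.0677) or without uninduced replicate 2 (0.0692), in which Kdr, the VEGF receptor, stood at 341 CPM against 107 CPM in replicate 1. Kdr (-2.55, edgeR adjusted p = 0.0127) lost its call without that library (0.0665) and without 12-day replicate 1 or 2 (0.0907 and 0.0606). Tie1, an endothelial receptor, fell by 2.28 and lost its call without 12-day replicate 1 or 2 (0.0754 and 0.0792). In smooth muscle and pericyte markers 3 of 12 rose and 6 fell (3 and 7 when adjusted over the list alone, median -1.49, adjusted p = 0.299), with Acta2 higher and Abcc9, a potassium channel subunit that cardiomyocytes also make, lower (-2.82). In the macrophage list edgeR called 0 of 15 genes (median 0, adjusted p = 0.984), as did DESeq2 and limma-voom, with 0 at an unadjusted p under 0.05. Of these genes 5 stood at 0 in all first set libraries and could not be called here. Only 1 of the 15 reached at least 5 CPM in both uninduced libraries.

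Camera called 16 of the 35 lists in this comparison and 0 with an estimated correlation (lowest adjusted p = 0.21), where 4 lists had an unadjusted p under 0.05. Because the 12-day animals carried Xist and the uninduced animals Y-linked transcripts, sex was entered as a term, which left 720 calls (462 higher, 258 lower) and ended 14 of 71 calls of genes followed by name, among them Klf4, Aqp7, Car4, Cox7a1, Sdha, Idh3b, Tnni3, Mylk3, Kdr, Tie1, Asns, Slc7a5 and Fos. Sex and group cannot be told apart inside this comparison. The term is therefore estimated from the second set libraries alone, and it assumes that their sex difference holds in the first set. Fitting these 2 groups alone ended the calls of Klf4 (adjusted p = 0.117), Aqp7, Car4, Kdr and Tie1. The count was 1580 without 12-day replicate 1, 1269 without 12-day replicate 2, and 1502 with library totals as the scaling, which moved the median of all genes by 0.23 and the share of higher genes from 53.3 to 77.4%.

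The withdrawal against 6-day comparison asks what changes once doxycycline is removed and the factors are switched off. Some contractile, ion channel, fuel use and interferon response genes were higher after withdrawal, and some biosynthetic and inflammatory genes were lower. Kcnip2, the potassium channel subunit, rose 6.33-fold, from 10.6 ± 2.13 to 66.8 ± 8.95 CPM (log2 fold change 2.66, SE 0.24, edgeR adjusted p = 0.00159). Tcap rose from 35.3 ± 8.61 to 112 ± 2.34 CPM, and Psat1 fell from 15.6 ± 3.24 to 1.14 ± 0.136 CPM. Of 13633 genes tested, edgeR called 661, of which 289 were higher and 372 lower (165 and 278 at least 2-fold). That balance depended on the method, with 460 higher and 276 lower by DESeq2, 529 and 390 with the strict filter, 380 and 346 with RLE factors and 390 and 367 with upper quartile scaling.

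Some genes of heart muscle lists rose. Of 25 contractile genes 5 rose, and 20 did so when adjusted over the list alone (median 0.78), among them Tcap (1.67), the M band protein Myom2 (1.19), the ventricular light chain Myl2 (1.08) and Mylk3 (0.81). Of 27 calcium handling and ion channel genes 8 rose (13 higher and 1 lower when adjusted over the list alone, median 0.53), with Scn4b (3.43), Hrc (1.51) and Kcnj2 (1.06) after Kcnip2. Fatty acid oxidation had 14 of 32 higher (23 when adjusted over the list alone, median 0.82), the tricarboxylic acid cycle 9 of 25 (22, median 0.72) and nuclear-encoded oxidative phosphorylation 12 of 73 (52, median 0.75). The camera adjusted p of these 5 lists, in the order given, was 6.08e-13, 8.52e-09, 1.22e-17, 1.27e-15 and 1.08e-23, and adjusted p = 0.36, 0.36, 0.36, 0.36 and 0.38 with an estimated correlation. Hadhb, the beta subunit of the trifunctional protein of fatty acid oxidation, rose from 48.6 ± 5.94 to 98.2 ± 15.5 CPM (1.01, SE 0.17, edgeR adjusted p = 0.0127), near Ech1 (0.97) and Hadh (1.03), another enzyme of that spiral. The malate dehydrogenase Mdh1 (0.93), Idh3b (0.92), Sdha (0.83), the complex I subunit Ndufs1 (0.89) and the cytochrome oxidase subunit Cox4i1 (0.89) rose as well. With library totals as the scaling the calls of these 5 genes ended (adjusted p = 0.486, 0.509, 0.593, 0.52 and 0.554), as did those of Hadhb (0.391), Ech1 (0.459), Hadh (0.376), Myom2 (0.181), Myl2 (0.305), Mylk3 (0.624) and Kcnj2 (0.346), and the 5 list medians were 0.63, 0.38, 0.67, 0.57 and 0.61. In the ketone body list (median 0.85) edgeR called 0 of 6 genes over all genes and 4 when adjusted over the list alone, with 4 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by limma-voom (camera adjusted p = 0.000614; adjusted p = 0.36 with an estimated correlation). Mitochondrial ribosomal proteins had a median of 0.24 and 0 of 44 genes called by edgeR, DESeq2 or limma-voom, with 3 higher at an unadjusted p under 0.05 (camera adjusted p = 0.0415; adjusted p = 0.80 with an estimated correlation), and the list was not called without any 1 library other than 6-day replicate 1 or withdrawal replicate 2 (adjusted p from 0.0602 to 0.880), nor with library totals (0.0755) or genes counted in both sets (0.0566).

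Of the interferon response genes 5 of 20 rose (13 when adjusted over the list alone, median 1.64, camera adjusted p = 1.76e-09; adjusted p = 0.36 with an estimated correlation). Ifit1, an antiviral RNA binder, rose from 4.75 ± 0.547 to 18.8 ± 0.172 CPM (1.98, SE 0.37, edgeR adjusted p = 0.0169), and the antiviral enzyme Rsad2 (2.00), Ifi44 (2.56) and the GTPase Gbp3 (2.24) rose with it. DESeq2 called 7 of the 20 and limma-voom 1, and the calls of these 4 genes ended with limma-voom (Ifit1 0.0556, Rsad2 0.0909, Ifi44 0.0743 and Gbp3 0.0809 as adjusted p) and without each of the 4 libraries of the comparison. Among the inflammatory cytokines and acute phase genes 5 of 9 fell (7 when adjusted over the list alone, median -2.17, camera adjusted p = 1.97e-07; adjusted p = 0.15 with an estimated correlation), including the protease inhibitor Timp1 (-3.12) and the TWEAK receptor Tnfrsf12a (-1.37). Macrophage markers had 0 calls of 15 (median -0.63, adjusted p = 0.0661) by edgeR, DESeq2 and limma-voom, and 0 at an unadjusted p under 0.05. Fibroblast markers had 0 calls of 14 (median 0.56, adjusted p = 0.111) by the same 3 tools and 0 at an unadjusted p under 0.05. Endothelial markers had a median of 0.61 with 0 of 16 genes called by the 3 tools and 0 at an unadjusted p under 0.05 (camera adjusted p = 0.0367; adjusted p = 0.80 with an estimated correlation). That list was not called without 6-day replicate 2 (adjusted p = 0.422) or withdrawal replicate 2 (0.854), nor with a replicate block (0.0648). Other large rises were in the lectin Lgals4 (2.60), the metalloprotease Mmp2 (2.47), Nrep (2.4), the amino acid transporter Slc36a2 (2.36) and Asb14 (2.26).

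A small part of the biosynthetic genes fell. In serine, one-carbon and nucleotide synthesis 4 of 24 fell (12 when adjusted over the list alone, median -0.78), with Psat1 (-3.76, SE 0.40, edgeR adjusted p = 0.00179), the folate enzyme Mthfd1l (-2.82) and the CTP synthase Ctps (-1.22). In ribosome biogenesis 1 of 24 fell (7 when adjusted over the list alone, median -0.49). These lists had a camera adjusted p of 4.28e-06 and 0.000105, and adjusted p = 0.15 and 0.59 with an estimated correlation. In the S phase list 4 of 30 fell (6 when adjusted over the list alone, median -0.66, camera adjusted p = 4.46e-05; adjusted p = 0.36 with an estimated correlation), including the replication factors Mcm10 (-2.13) and Mcm6 (-1.59) and Uhrf1 (-1.64). In the mitosis list edgeR called 0 of 35 genes, with 6 lower at an unadjusted p under 0.05, 1 lower by DESeq2 and 0 by limma-voom. Its median of -0.63 was called by camera (adjusted p = 0.000635; adjusted p = 0.77 with an estimated correlation), but not without 6-day replicate 2 (adjusted p = 0.295). Hmmr (-0.32) and Top2a (-0.46), followed because of their 12-day change, were not called, nor was Anln (-1.60, adjusted p = 0.0620; called with DESeq2, 0.00192, with these 2 groups alone, 0.0193, and with library totals, 0.00656). Cytosolic ribosomal proteins had a median of -0.20 and 0 of 52 genes called by edgeR, DESeq2 or limma-voom, with 9 lower and 1 higher at an unadjusted p under 0.05 (camera adjusted p = 0.0155; adjusted p = 0.80 with an estimated correlation). That direction turned without 6-day replicate 1 (adjusted p = 0.980), and the list was not called without withdrawal replicate 2 (0.618). Without 6-day replicate 1 the ribosome biogenesis list was not called either (0.0621).

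Fetal and stress genes had 5 of 30 lower (6 when adjusted over the list alone, median -0.08, adjusted p = 0.137). The actin binders Cnn1 (-4.20) and Actn1 (-1.25), Tnnt1 (-1.76) and Acta2 (-0.98) fell, whereas Myh7 (0.29) and Nppa (0.60, edgeR adjusted p = 0.272) were not called. Nppa stood at 113 ± 40.5 CPM after withdrawal and 74.6 ± 19.4 CPM at 6 days. Of 16 YAP targets 3 fell (5 when adjusted over the list alone, median -0.19, camera adjusted p = 0.00271; adjusted p = 0.36 with an estimated correlation), with Tgfb2 (-1.55) and Nt5e (-1.39). In the matrix list 1 of 25 rose and 2 fell, and the list was not called (median -0.12, adjusted p = 0.804). Among called genes with a mean of at least 5 CPM over the 2 groups and separated replicates, large falls beyond the factors were in Acan, a cartilage proteoglycan with 0 counts after withdrawal and 15.5 ± 5.72 CPM at 6 days, the G protein subunit Gnal (-5.17), the actin regulator Avil (-5.10), the tubulin Tubb2b (-4.59), the protease inhibitor Serpinb1a (-4.52), the matrix protein Npnt (-4.45) and the chemokine receptor Cxcr6 (-4.27).

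Camera called 18 of the 35 lists in this comparison and 0 with an estimated correlation (lowest adjusted p = 0.15), where 3 lists had an unadjusted p under 0.05. The count of 661 rested on each of the 4 libraries, since it was 84 without 6-day replicate 1, 31 without 6-day replicate 2, 209 without withdrawal replicate 1 and 177 without withdrawal replicate 2, and in 149 of 236 such repeats for called genes followed by name the call was lost. The calls of Pou5f1, Sox2, Myc, Kcnip2, Tcap, Psat1, Nt5e, Cdkn1a, Gnal, Avil and Tubb2b held without each of these libraries. With library totals as the scaling it was 267, the median of all genes moved by -0.15 and the share of higher genes went from 43.7 to 15.7%. Calls of Tnfrsf12a, Ctps, Acta2, Pfkm, Eno3 and Acaa2 ended there too, those of Lgals4, Mmp2, Nrep, Serpinb1a, Scn4b, Ctps and Uhrf1 with limma-voom, and those of Ifi44, Mmp2, Acan, Sdha, Scn4b and Ctps with a term for sex.

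**Figure D2:**
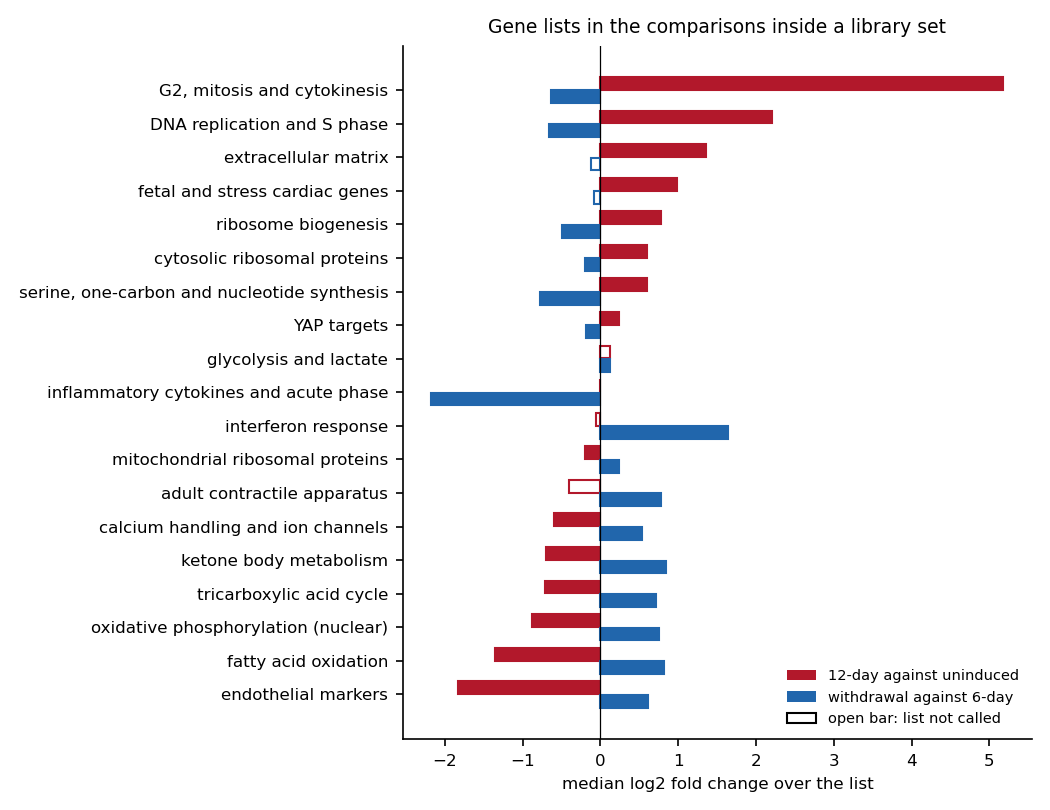
Bars give the median log2 fold change over the tested genes of each list for the 2 comparisons inside a library set, and open bars are lists that camera did not call. The mitosis list has medians of 5.18 and -0.63, and the fatty acid oxidation list -1.36 and 0.82; with library totals as the scaling the mitochondrial ribosomal list turns to 0.13 in the 12-day comparison and the glycolysis list to -0.03 in the withdrawal comparison.

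**Figure D3:**
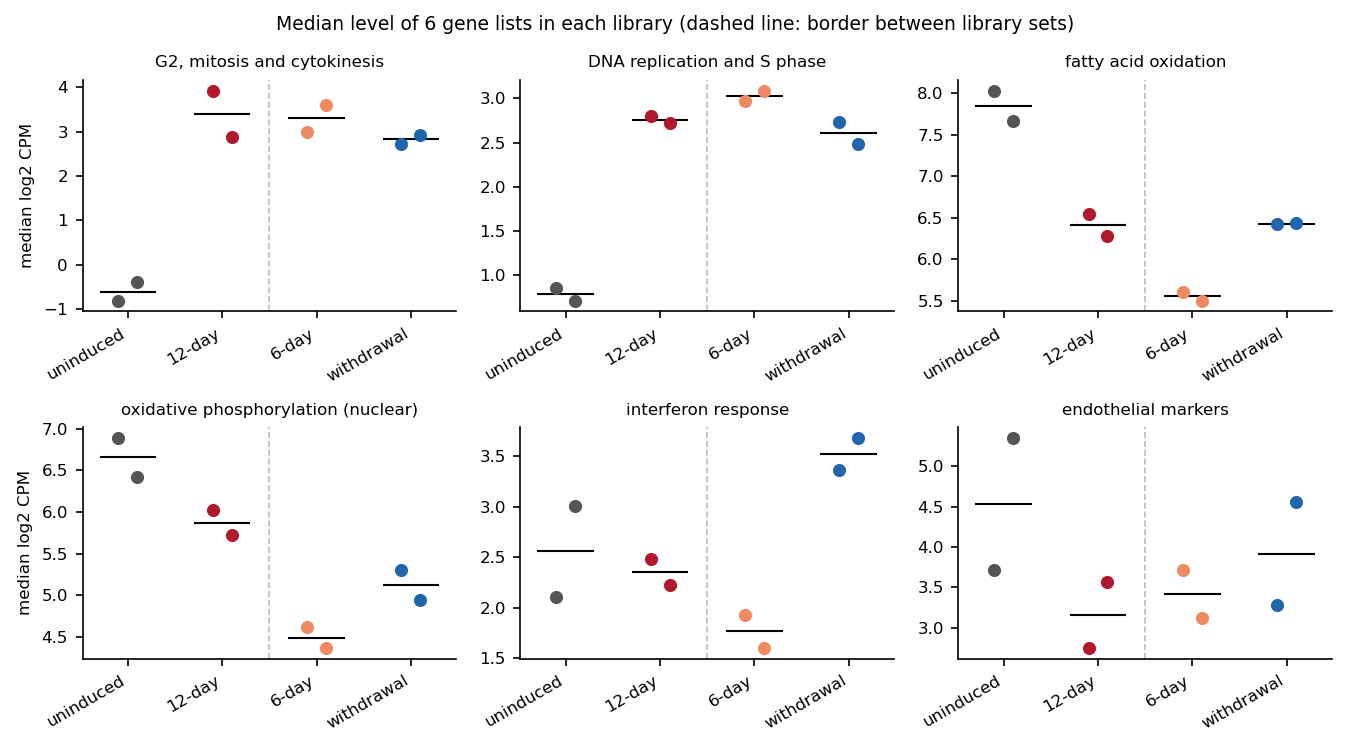
Median log2 CPM over the genes of 6 lists in each library, where points are libraries, horizontal lines are group means and the dashed line is the border between the library sets. Levels on either side of the dashed line differ in both group and library set.

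A comparison of the changes inside the first set with those inside the second was added after the library sets were seen. Genes that were raised at 12 days were mostly lower after withdrawal than at 6 days, and genes that were lowered were mostly higher. Of the 12567 tested genes counted in both library sets, 308 were raised in the first comparison and lowered in the second, against 45.6 by chance, and 231 were lowered and then raised, against 31.4 by chance. Psat1, Tgfb2 and Tnnt1 are among the former and Kcnip2, Hrc and Acaa2 (-2.13 and 0.95) among the latter. A change in the same direction was called for 3 genes: the clock factor Arntl (-1.54 and -7.63), the matrix protein Comp (4.01 and 8.27) and the light chain Myl6b (3.23 and 1.91). Of the genes called at 12 days, 91.0% had the opposite sign in the second comparison. The log2 fold changes had a Pearson r of -0.57 across genes, which are not independent replicates. The comparisons share no libraries, and their 539 reciprocal genes became 75 and 28 without 6-day replicates 1 and 2, 186 and 155 without withdrawal replicates 1 and 2, 316 without 12-day replicate 2, and 900 without uninduced replicate 2. The count was 221 with a term for sex, 196 with library totals as the scaling and 349 with limma-voom.

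**Figure D4:**
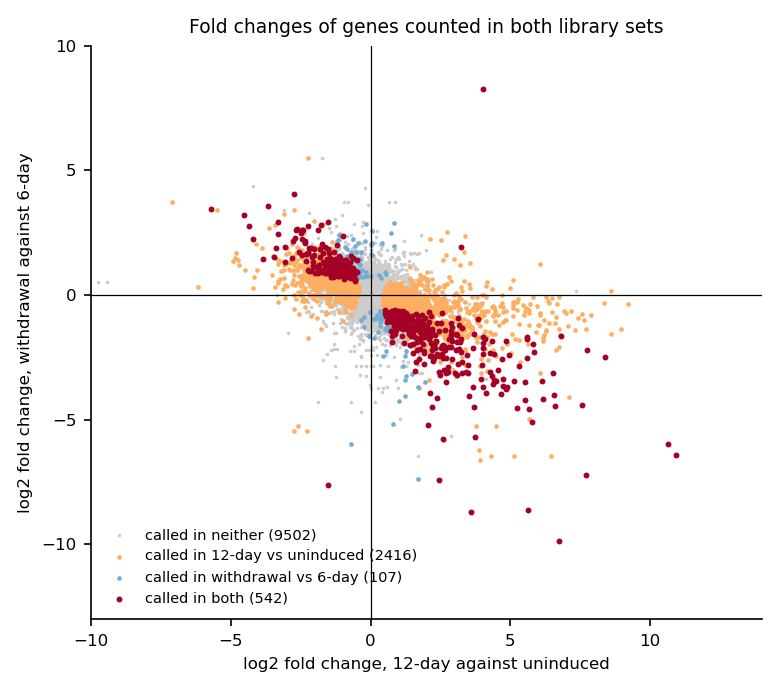
Each point is 1 of 12567 genes, with its log2 fold change at 12 days against uninduced on the horizontal axis and after withdrawal against 6 days on the vertical axis, both from edgeR. Colours mark genes called in neither comparison (9502), in the first (2416), in the second (107) or in both (542), and genes at 0 counts in a group are drawn at a fitted value that depends on the prior count.

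The 6-day against uninduced comparison asks what differs after 6 days of doxycycline and factor expression, and it crosses the library sets. Contractile genes were lower and mitosis genes higher in the 6-day libraries. Myh6, the adult myosin heavy chain, stood at 664 ± 206 against 27870 ± 5760 CPM (log2 fold change -5.39, SE 0.40, edgeR adjusted p = 1.18e-05), and the light chain Myl3 (-5.93) and myoglobin (Mb, -5.45) were lower too. Hmmr was higher by 7.15, Uhrf1 by 7.07, Timp1 by 7.24 and Npnt by 7.46, and Acan was at least 52.2-fold higher. Of 35 mitosis genes 34 were higher (median 4.75) and of 25 contractile genes 23 were lower (median -2.51), with a camera adjusted p of 1.57e-17 and 2.37e-29, and adjusted p = 0.35 and 0.20 with an estimated correlation. Of the macrophage markers 7 of 15 were higher (median 1.64, camera adjusted p = 0.00328; adjusted p = 0.62 with an estimated correlation), but 5 of these 7 stand at 0 in all first set libraries. Of 14 fibroblast markers 5 were higher, 1 of them at 0 in the first set, and the list was not called (median -0.12, mean 0.69, adjusted p = 0.478). Of the endothelial markers 8 of 16 were lower (median -1.53, camera adjusted p = 0.00265; adjusted p = 0.62 with an estimated correlation). EdgeR called 5415 genes (3236 higher, 2179 lower), of which 1025 stand at 0 in all libraries of 1 set. Among the 12463 genes tested that are counted in both sets it called 4205 (2112 higher, 2093 lower). The count was 3238 without 6-day replicate 1 and 2921 without 6-day replicate 2.

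The withdrawal against uninduced comparison asks what remains 6 days after doxycycline is removed and the factors are switched off, and also crosses the sets. Cell division genes and Nppa were higher and contractile genes lower in the withdrawal libraries. Top2a stood at 39.1 ± 6.36 against 1.28 ± 0.960 CPM (4.91, SE 0.52, edgeR adjusted p = 0.000413), and Hmmr (6.82), Ckap2l (5.83), Knstrn (5.25) and Nppa (5.09) were higher as well. Of the factors, Klf4 (-0.47), Myc (1.30) and Pou5f1 were not called (adjusted p = 0.352, 0.132 and 0.0839), and Sox2 was called from 1 and 2 counts against 0 and 0 (0.0440), a call that ended with DESeq2 (0.0948), the strict filter (0.0501), a replicate block (0.0567), genes counted in both sets (0.0588) and a term for sex (0.0554), and without each library of the 2 groups (0.0679 to 0.205). Pou5f1 was called with DESeq2 (0.0471) and without withdrawal replicate 1 (0.0243), Myc without withdrawal replicate 1 (0.0384), Klf4 as lower without uninduced replicate 1 (0.0254), and all 3 as higher with library totals as the scaling. In the mitosis list 32 of 35 genes were higher (median 4.04) and in the contractile list 22 of 25 lower (median -1.71), with a camera adjusted p of 1.80e-21 and 4.93e-31, and adjusted p = 0.33 and 0.33 with an estimated correlation. Macrophage markers had 5 of 15 higher (median 1.29, camera adjusted p = 0.0119; adjusted p = 0.64 with an estimated correlation), all 5 of them at 0 in the first set. Fibroblast markers had 5 of 14 higher (1 of them at 0 in the first set, median 0.79, camera adjusted p = 0.0273; adjusted p = 0.68 with an estimated correlation). In the endothelial list (median -0.92, camera adjusted p = 0.0273; adjusted p = 0.76 with an estimated correlation) edgeR called 0 of 16 genes, with 3 lower at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom. EdgeR called 3007 genes (1718 higher, 1289 lower), 927 of them at 0 in all libraries of 1 set, and 1791 (657 higher, 1134 lower) among genes counted in both sets. The count was 1543 without uninduced replicate 1 and 1372 when only these 2 groups were fitted.

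At day 12, continued induction against withdrawal (12-day against withdrawal) again crosses the sets. Pou5f1 (6.23), Sox2 (6.36), Myc (4.85) and Klf4 (1.71, edgeR adjusted p = 0.00604) were higher in the 12-day libraries, and Klf4 was lower with library totals as the scaling (-1.33, adjusted p = 0.00297), which moved the median of all genes by -2.98. Myh7 stood at 5040 ± 147 against 629 ± 115 CPM (8.02-fold), Avil (4.38) and Gnal (4.32) were higher (Myh7 and Gnal not called with library totals, adjusted p = 0.958 and 0.0745), and Gadd45a (-2.86) and Ces1d (-2.72) lower. Of the interferon response genes 6 of 20 were lower (median -1.25), and 7 of 35 mitosis genes were higher (median 1.18). EdgeR called 3237 genes (1505 higher, 1732 lower), 931 of them at 0 in all libraries of 1 set, and 2032 (1327 higher, 705 lower) among genes counted in both sets. The count was 1059 and 1140 without 12-day replicates 1 and 2, 2118 with a term for sex and 2137 with DESeq2.

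The 12-day against 6-day comparison, 12 against 6 days of induction, showed no called difference in the factors: Pou5f1 -0.20, Sox2 0.37, Klf4 0.45 and Myc 0.69 (edgeR adjusted p = 0.734, 0.380, 0.394 and 0.0886). Myc was called when only these 2 groups were fitted (0.76, adjusted p = 0.0116), and with library totals as the scaling all 4 were called lower (-3.37, -2.81, -2.74 and -2.47), near the shift of all genes given below. The contractile genes Actc1, cardiac actin (4.87, 5349 ± 304 against 183 ± 57.6 CPM), and Myl3 (4.95), and myoglobin (Mb, 4.53), were higher in the 12-day libraries. EdgeR called 2228 genes (1070 higher, 1158 lower), 941 of them at 0 in all libraries of 1 set, and 1077 (910 higher, 167 lower) among genes counted in both sets. Leaving out 1 library gave 626 to 918 calls (626 and 871 without 12-day replicates 1 and 2, 918 and 693 without 6-day replicates 1 and 2). In these 4 comparisons library totals as the scaling moved the median of all genes by 3.43, 3.29, -2.98 and -3.13, so that 99.5, 99.4, 0.7 and 0.5% of the called genes were higher in place of 59.8, 57.1, 46.5 and 48.0%.

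The calls at 6 and 12 days against the same uninduced libraries overlapped in 2247 genes of the same direction (1210 higher, against 374.56 by chance, and 1037 lower, against 221.21), with 52 in opposite directions. Hmmr, Uhrf1, Timp1 and Myc are among the genes higher in both. Simulated unchanged groups against the same uninduced libraries gave a mean of 0 shared calls in 20 draws, but a Pearson r of 0.44 from the shared libraries alone, against 0.46 observed (0.81 over genes counted in both sets), and a covariance of 0.09 against 1.12 (1.22). The simulated groups held no true change and no difference between library sets, so shared calls were unlikely there from the start. Part of the excess over chance may come from the shared uninduced libraries, which are too few to divide. The overlap was 1398 and 1071 without 12-day replicates 1 and 2, and 1437 without 6-day replicate 2.

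Of the 5415 genes called at 6 days against uninduced, 605 were called in the opposite direction after withdrawal, against 134.49 by chance and 0.15 in simulated unchanged withdrawal, and 2623 were still called in the same direction against uninduced. The simulated withdrawal held no true change, so opposite calls were unlikely there from the start. The figure by chance does not allow for the 6-day libraries, which enter both comparisons with opposite sign. Psat1, Timp1, Npnt, Hadhb and Kcnip2 changed inside the second set, whereas Hmmr and Top2a stayed above uninduced. The median ratio of the withdrawal to the 6-day log2 fold change was 0.66, against 0.96 in the simulation. Among genes counted in both sets 641 of 4205 were called in the opposite direction and 1527 were still called, with a ratio of 0.57. The set difference enters both parts of that ratio. The count of 605 was 81 and 30 without 6-day replicates 1 and 2, 198 and 167 without withdrawal replicates 1 and 2, and 1015 and 1056 without uninduced replicates 1 and 2. The count of 2623 was 1324 without uninduced replicate 1, 1658 without 6-day replicate 2, and 1649 and 1669 without 12-day replicates 1 and 2.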

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

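The difference between the changes inside the 2 library sets was tested after the sets were seen, and the tests on macrophages and on a lasting contractile change were chosen after the result was seen; the other tests were written before.

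If withdrawal undid what induction does, and 6 and 12 days of induction acted alike, a gene's log2 fold change at 12 days against uninduced and its change after withdrawal against 6 days would sum to about 0, and any fixed offset of a library set cancels in that sum. The second condition cannot be tested across the sets, so a sum away from 0 does not separate an incomplete return from an effect of longer induction. Compression of fold changes in the second set would not cancel in the sum. Neither would sex, which coincides with group in the 12-day against uninduced comparison alone. Both stay open as sources of a sum away from 0. The sum differed from 0 in 94 genes by an interaction term in edgeR (84 above 0 and 10 below), a count of 3 with a term for sex or without 6-day replicate 2, and of 216 without uninduced replicate 2. Among genes followed by name it was above 0 for spindle and cell cycle genes: Hmmr 8.01 (SE 1.03, adjusted p = 0.0159), Ckap2l 6.62, Iqgap3 6.30, Dlgap5 6.25, Knstrn 6.19, Top2a 5.51 (SE 0.64, adjusted p = 0.0117), Kntc1 5.21, Uhrf1 5.17, Bub1b 4.69 and Anln 4.6. Among fetal heart genes it was above 0 for Nppa 5.68 (SE 0.47, adjusted p = 0.00281), Myh7 5.26 (SE 0.36, adjusted p = 0.000231), Tnnt1 3.83 and Acta2 2.87. It was also above 0 for Eln 4.40, Mthfd2 3.26, Ifit1 2.81, Rpl3 2.18, Pgam1 2.16, Rplp1 1.75, Pfkp 1.69, Npm1 1.41 and Nt5e 1.27, and below 0 for Gnal -4.36, Rpl3l -2.40, Abcc9 -1.36 and Ech1 -1.23. These genes changed less, or not at all at the threshold, after withdrawal than at 12 days, except Gnal and Ifit1, which changed more.

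Camera called 13 lists for the same sum, none of them with an estimated correlation (adjusted p from 0.21 to 0.69 for these lists). The median sum was 4.37 for mitosis (10 of 35 genes called), 1.47 for S phase (4 genes), 1.26 for extracellular matrix, 1.23 for the interferon response, 1.07 for fibroblast markers, 0.87 for fetal and stress genes (6 genes), 0.37 for the contractile apparatus, 0.35 for glycolysis, 0.35 for cytosolic ribosomal proteins and 0.29 for ribosome biogenesis. It was -0.55 for fatty acid oxidation, -0.78 for immediate early genes and -1.12 for endothelial markers.

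The first pattern is that mitotic genes rose at 12 days (median 5.18) and stood 4.04 above uninduced 6 days after withdrawal. An abundance-dependent difference between the library sets is argued against, since 0 of 10000 lists matched on the uninduced level reached 4.04 (their medians ran from 0.13 to 2.67). So is sex, with a median female minus male difference of 0.28 over the list inside the second set, provided that this difference also holds in the first. A gain of macrophages is argued against for the 12-day rise alone, by a median gain of 0.0434 CPM over 10 of their markers (range -1.56 to 0.79) beside 9.1 CPM for the mitosis list. Mrc1 and Lyz2, the most abundant, stood at 6.40 to 17.32 and 4.20 to 13.70 CPM in the uninduced and 6.40 to 14.19 and 5.81 to 9.97 CPM in the 12-day libraries. Marker levels cannot show whether macrophages already present began to divide, so that source stays open. After withdrawal macrophages stay open, as the same markers stood 1.37 CPM above uninduced (range 0.73 to 5.07) beside 5.4 CPM for the mitosis list, across the library sets, and so do fibroblasts, whose 13 markers gained a median of 1.90 CPM at 12 days (range -21.63 to 91.2), and an offset of single genes between the sets, which was not tested. Division of the cardiomyocytes themselves may be the source, as a hypothesis that these data cannot separate from those.

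The second pattern is that the 12-day and uninduced groups differ in the sex of the animals, so sex could lie behind their calls. As the whole cause it is argued against by the calls that held with a term for sex, provided that the sex difference of the second set also holds in the first. Of 2958 called genes 55.6% had a female minus male difference in the second set of the same sign. That share cannot decide, because a sex difference adds to the spread inside both second set groups and so makes a call less likely. The female minus male difference was called in 5 genes, of which 0 were called at 12 days. Across genes it had a correlation of 0.21 with the 12-day change. With a term for sex 720 genes were called, 707 of them among the 2962, and of the 2962 calls 99.9% kept their sign. Over the 2255 calls that ended, the median size of the log2 fold change went from 1.03 to 0.97 and the median SE from 0.24 to 0.36 (1.20 to 1.15, with the same SEs, over all calls), so most of the loss came with a wider error. Among calls with an SE, the change became smaller in 60.8% of those that ended and in 38.1% of those kept. For single genes sex stays open, as for Kdr, which went from -2.55 to -1.55.

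The third pattern is that contractile genes stood lower than uninduced in both groups of the second set (medians -2.51 and -1.71), whereas at 12 days, inside the first set, the median was -0.40. Compression of abundant transcripts in the second set could produce this: 2 of 10000 lists matched on the uninduced level fell as low as -1.71 (median -1.10, lowest -1.93), but 10 of the 25 genes lie over 2-fold above their matches (medians 1360 and 884 CPM), so the match is too weak to decide. The length of the gene stays open too, with a rank correlation of 0.38 between the change and the RefSeq span over 25 genes. A lasting change after induction cannot be told apart from the library set, since 0 of the groups have libraries in both sets. With library totals as the scaling the contractile medians were 0.93, 1.62 and -0.05 for 6-day, withdrawal and 12-day against uninduced. That scaling moved the median of all genes by 3.43, 3.29 and 0.23 in the same order.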

How the results depend on the processing

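Alternatives chosen after seeing the data are the sex term, genes counted in both sets, the crossed block, limma on the deposited normalized values, and all those of the reciprocal and difference counts; the others were planned. The cause of a moved value was not tested unless fewer genes or libraries, or the scaling itself, give it by construction. Library totals include mitochondrial counts, which were 76.18 to 86.29% of the total in the first set and 0% in the second. That scaling therefore moves comparisons across the sets by construction. With library totals as the scaling the counts of called genes were 1502 (12-day against uninduced), 267 (withdrawal against 6-day), 13238 (6-day against uninduced), 13352 (withdrawal against uninduced), 13363 (12-day against 6-day), 13103 (12-day against withdrawal) and 169 for the difference between sets. That scaling gave 196 reciprocal genes, 11 called lists for withdrawal against uninduced, and turned Klf4 to -1.33 in 12-day against withdrawal. The sex term gave 720 (12-day against uninduced), 2118 (12-day against withdrawal), 3 for the difference and 221 reciprocal genes. Genes counted in both sets gave 1791, 1077 and 2032 calls, and the strict filter (5 CPM in 2 libraries) 1811, 1284 and 2065, for withdrawal against uninduced, 12-day against 6-day and 12-day against withdrawal, by fewer genes tested; 1527 genes counted in both sets were still called after withdrawal. Fitting 2 groups alone gave 1372 for withdrawal against uninduced. DESeq2 gave 2137 for 12-day against withdrawal and 209 for the difference, and limma-voom 349 reciprocal genes. Replicate numbers do not pair the libraries (correlations of replicate deviations from -0.11 to 0.25), and a block on them gave 1025 calls for withdrawal against 6-day and 3327, 5571, 3161, 2396 and 3438 for the others (12-day against uninduced, 6-day and withdrawal against uninduced, 12-day against 6-day, 12-day against withdrawal); crossing the numbers in the 6-day group gave 2453 for 12-day against 6-day.

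With an estimated correlation 0 lists were called in each of the 6 comparisons and 0 for the difference; fry, which asks if a list differs from no change and not from the other genes as camera does, called 3 (withdrawal against 6-day), 13 (withdrawal against uninduced) and 0 (difference). In 12-day against uninduced it called 13 as well, and did not call 6 lists that camera called: oxidative phosphorylation (adjusted p = 0.053), cytosolic ribosomal proteins (0.0547), ketone bodies (0.07), extracellular matrix (0.0908), endothelial markers (0.22) and mitochondrial ribosomal proteins (0.334). Without 1 library the counts ran from 1269 to 2887 (12-day against uninduced), 31 to 209 (withdrawal against 6-day), 2921 to 4402 (6-day against uninduced), 1543 to 2401 (withdrawal against uninduced), 626 to 918 (12-day against 6-day), 1059 to 2359 (12-day against withdrawal) and 3 to 216 (difference). Called lists ran from 15 to 19, 16 to 20, 18 to 21, 14 to 19, 12 to 15, 16 to 18 and 13 to 16 in the same order, the overlap from 1071 to 2412, opposite calls after withdrawal from 30 to 1056, genes still called from 1324 to 2070 and reciprocal genes from 28 to 900. A lone library was assumed to vary like the other groups. Without 6-day replicate 1 the list cytosolic ribosomal proteins turned (adjusted p = 0.98, against 6.5e-07 without 6-day replicate 2), and without withdrawal replicate 1 the list mitochondrial ribosomal proteins did (0.88, against 1.61e-05 without withdrawal replicate 2), both in withdrawal against 6-day. Of the genes followed by name, calls ended with the sex term for 14 of 71 at 12 days and 6 of 59 after withdrawal, with library totals for 6 and 19, and with limma-voom for 1 and 11; leaving out 1 library ended 7 of 283 and 149 of 236. Limma on the deposited normalized values called 2718 and 948 genes in the comparisons inside a set. With 1477245 to 1692421 counts per library, the second set limits what withdrawal against 6-day can show.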

Other observations

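No test in this part was planned beyond the lists and comparisons above; the checks of the deposited normalized table and of the abundance gradient were chosen after the result was seen.

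Some cell cycle inhibitors and stress genes changed in both comparisons inside a set. Cdkn1a, the p21 inhibitor of the cell cycle, rose at 12 days from 1.44 ± 0.371 to 16.2 ± 1.94 CPM (log2 fold change 3.48, SE 0.27, edgeR adjusted p = 5.29e-05) and fell after withdrawal from 22.1 ± 1.05 to 3.11 ± 0.321 CPM (-2.83, SE 0.27, adjusted p = 0.00165). Gadd45a, a growth arrest gene, went the other way, falling from 7.66 ± 0.234 to 1.49 ± 0.400 CPM at 12 days (-2.35) and rising from 2.59 ± 0.167 to 11 ± 3.12 CPM after withdrawal (2.08). The p53 list holding both was called in neither comparison, with 5 higher and 3 lower of 20 at 12 days (median 0.25, adjusted p = 0.299) and 1 higher and 3 lower after withdrawal (median -0.19, adjusted p = 0.207). Asns, which makes asparagine, and the amino acid transporter Slc7a5 rose at 12 days (3.40 and 2.76, not called with a term for sex) and fell after withdrawal (-3.09 and -2.89). Their list, the integrated stress and unfolded protein response, was not called either: 5 of 22 rose and 4 fell at 12 days (median -0.25, mean 0.37, and 0.03 as the median with library totals; adjusted p = 0.921), and 3 fell after withdrawal (median -0.27, adjusted p = 0.397). Among immediate early genes Jun (-1.19) and Fos (-1.17) fell at 12 days, calls that ended with library totals as the scaling (adjusted p = 0.151 and 0.196) and, for Fos, with a term for sex (0.108), with 1 higher and 5 lower of 18 (median -0.41, adjusted p = 0.0962), and 1 was lower after withdrawal (median -0.24, adjusted p = 0.137).

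Glycolytic isoforms changed in part. At 12 days the aldolase isoform Aldoc (6.57) rose, as did Pgam1 (2.51) and Pfkp (2.38), isoforms made in many tissues. The insulin-regulated glucose transporter Slc2a4 fell (-1.59), with 9 higher and 6 lower of 24 in the list (10 and 7 when adjusted over the list alone, median 0.12, camera adjusted p = 0.301). After withdrawal the muscle isoforms Pfkm (1.06) and Eno3 (1.07) rose and Aldoc (-4.01) and the lactate exporter Slc16a3 (-4.49) fell, with 5 higher and 2 lower (10 and 3 when adjusted over the list alone). That list had a median of 0.12, a mean of -0.07 and a median of -0.03 with library totals, and was called by camera (adjusted p = 0.0265; adjusted p = 0.59 with an estimated correlation), but not without 6-day replicate 2 (0.0864) or withdrawal replicate 1 (0.152), nor with library totals (0.231). Rpl3 rose at 12 days from 16.5 ± 3.46 to 97.6 ± 5.78 CPM (edgeR adjusted p = 6.48e-05) as its muscle paralog Rpl3l fell from 194 ± 45.2 to 13.4 ± 3.39 CPM (adjusted p = 3.43e-05).

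Further lists were not called at 12 days, or not after withdrawal, or in neither. At 12 days edgeR found 1 of 7 pluripotency genes higher and 1 lower (median 0, adjusted p = 0.984), 3 of 11 epithelial genes higher and 1 lower (median 0.56, adjusted p = 0.355), 1 of 14 NRF2 genes higher and 2 lower (median 0.16, with camera's direction down, adjusted p = 0.984), 1 of 20 interferon genes lower (median -0.06, 0.06 with library totals, adjusted p = 0.787), and 3 of 9 inflammatory genes higher, among them Timp1 (6.53) and Tnfrsf12a (2.21) (median 0, mean 1.24, adjusted p = 0.0577). It found 2 of 9 epicardial markers higher (median 1.22, adjusted p = 0.0888), 1 of 13 non-polyadenylated transcripts higher (median 0.15, adjusted p = 0.647), 0 of 3 erythroid (median -1.27, adjusted p = 0.355, with 1 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom), 0 of 3 Schwann (median 0.18, mean -0.05, adjusted p = 0.984) and 0 of 9 genes of the mitochondrially encoded list (median -0.53, adjusted p = 0.104), the last 2 with 0 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom. After withdrawal it found 1 of 7 pluripotency genes lower (median 0.23, mean -0.39, adjusted p = 0.804), 1 of 14 NRF2 genes higher (median -0.32, adjusted p = 0.299), and 1 of 12 smooth muscle and pericyte markers higher and 3 lower (median 0.52, mean -0.12, adjusted p = 0.983). After withdrawal edgeR called 0 of 11 epithelial (median -0.66), 0 of 3 erythroid (3.05), 0 of 3 Schwann (0.61), 0 of 9 epicardial (0.40, with camera's direction down), 0 of 8 atrial (0.50) and 0 of 13 non-polyadenylated genes (0.12, and -0.04 with library totals), with adjusted p of 0.804, 0.299, 0.804, 0.976, 0.0853 and 0.685 by camera. At an unadjusted p under 0.05 these had 3, 2, 2, 0, 2 and 1 genes; DESeq2 called 1 epithelial and 1 atrial gene, limma-voom 1 epithelial gene, and both 0 in the rest. Of the 9 genes in the mitochondrially encoded list 8 had 0 counts in the second set. The other, Gm10925, entered through an alternative symbol of a listed mt- gene and may not be mitochondrially encoded. It had 1 to 5 counts per library in the second set and was not called (0.83, adjusted p = 0.712).

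The deposited normalized table gives each gene the same mean in both library sets, to within 5.0e-09 over 15183 genes. The difference of withdrawal from uninduced therefore equals that of 12-day from 6-day in it (correlation 1.0 across genes), whereas in the raw counts that correlation was -0.74 over 3268 genes with at least 100 counts in every library. Inside a set the table followed the raw counts (correlation 0.9999 across genes). In the raw counts the median change of withdrawal from uninduced ran from 1.22 in 870 genes under 1 CPM in the uninduced group to -1.95 in 52 genes at 1000 CPM or more (-1.48 in the 19 of these outside all lists), and that of 6-day from 12-day was -2.29 in the latter. Inside the first set the median of 12-day from uninduced was -0.59 in those 52 genes.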
